A study of Homo sapiens with 2 samples.

How the data were processed

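The series held 2 samples of HCT116, an established human colorectal cancer cell line. Per the labels' protocols, 1000000 cells were electroporated with 100 pmol of a miR-1 precursor or of a negative-control precursor, which has no intended target. Total RNA was taken 48 h later, and 700 ng was amplified, labelled with Cy3 and hybridised to 1-colour Agilent whole human genome arrays. Each group had 1 array, so the groups had no replicates.

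The deposited scanner files gave each spot's processed signal as an intensity on a linear scale, and, per the file headers, the authors' scanner software (Agilent Feature Extraction, version 9.5 in the submitters' processing notes) had subtracted the background with a spatial detrending surface and divided out a multiplicative trend within each array. The same files gave flags for spots well above background, saturated spots and outlying spots. No scaling between arrays was recorded in the headers or the labels. The value table of the series held the same intensities as deposited, since 45015 of its 45015 entries equalled the processed signal on the control array and 45015 on the miR-1 array. That alternative was therefore identical to the main setting. Per the file headers, both arrays lay on the same slide and were scanned in the same run, so slide and scan did not separate the groups.

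Each array had 45015 spots, of which 43376 carried 41000 different probes for human transcripts and 1639 were controls. Control spots and outlying spots (72 on the control array and 106 on the miR-1 array) were left out. The log2 processed signal was averaged over the spots of a probe, and the array's 75th percentile was subtracted. The change was the miR-1 array minus the control array. Probes were named through their accession in a table of RefSeq genes (assembly GRCh38.p14, used for names alone): 23434 matched by accession, 2317 by current symbol and 1043 by older symbol. The other 14206 probes kept the name in the file and were counted apart. A gene was measured if at least 1 probe was well above background on at least 1 array, and its value came from its probe with the highest mean signal. Probe coordinates are those in the files, on build hg17 (NCBI35), and were not converted.

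Counts of genes past 2-fold covered genes well above background on both arrays. A gene above background on 1 array alone was given as a bound, the bright signal over the higher of the dim signal and the lowest signal well above background on that array. List counts used the bound for such genes.

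With 1 array per group no test across samples was possible, and no p-value or standard error was computed. The number of arrays limits the precision, and no difference reported here has a replicate check. For a gene list, the median change was placed among the medians of 10000 random lists of the same size, drawn from measured genes in the same 20 classes of mean signal. That percentile describes these 2 arrays only, and a median outside the central range from the 2.5th to the 97.5th percentile is said to stand apart. Of 264 probes spotted 10 times, the 209 with at least 5 usable spots described the precision, as the SD over spots of the log2 change, in 5 classes of signal. This spot SD leaves out labelling, hybridisation, transfection and culture.

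Before the data were examined, the comparisons, the alternatives, the 22 gene lists and the rule for named genes were fixed. The rule took the 12 most lowered and 12 most raised genes whose measured probes all changed in the same direction, by at least 2-fold. It added the 4 largest bounds in each direction. From each list it took up to 4 members changed at least 1.5-fold, or otherwise the 2 brightest. From the published miR-1 targets it took every member changed at least 1.5-fold and 8 fixed genes, among them ANXA2, BDNF, MET, TAGLN2, TWF1, PTMA and LASP1. The most changed genes among the brighter genes, and further list members named to describe a list, were chosen after their values were seen. Of the measured published targets, 4 were also on the actin list, 3 on the pentose phosphate list, 2 on the chaperone list, 2 on the Wnt list and 1 on the list of epithelial-mesenchymal transition.

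The planned search for miR-1 sites in 3′ untranslated regions needed transcript sequences, and none was available here, so those planned results were not computed. In its place, and chosen after seeing the files, the same words were searched in the 60-base sense-strand probe sequences given in the files. A probe covers only a small part of a transcript, so a gene without the word in its probe can still hold sites elsewhere. Hexamers were ranked by the mean change of genes with the word minus that of genes without it, over words present in at least 20 probes.

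Alternatives were quantile normalisation, centring on the median, normexp background correction of the raw signals (limma 3.58.1 in R 4.3.3, offset 50), other filters on dim probes, the mean over a gene's probes, other size thresholds, and outlying spots kept. Scaling on external spike-in transcripts, random lists matched also on probe GC content and subtraction of the median change of the 200 nearest spots were added after seeing the data. An alternative value of a list was called moved if it differed by more than the SD of the list's random medians. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

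The steps were tested on simulated data with the real signals and spot SDs over 12697 genes. Of 50 genes changed 2.5-fold, 50 passed 2-fold in the right direction, as did 50 of 50 changed 3-fold and 49 of 49 changed 4-fold. Of 50 changed 1.5-fold, 0 passed 2-fold. Among 12236 unchanged genes 0 passed. Their simulated noise was spot error alone, whereas the real change had an SD of 0.32 over genes above background on both arrays. That 0 is therefore no false-call rate for the real arrays. A list shift of 0.3 was recovered as 0.26, and 11 of 200 unshifted lists fell outside the central range. Those lists were random genes, so they do not show how often a list of related genes would stand apart. A hexamer given a shift of -0.15 ranked 1 among all words by standardised difference. Its rank by mean difference was not tested.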

Results

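HCT116 colorectal cancer cells that had received the miR-1 precursor were compared with cells that had received a negative-control precursor, 48 h after transfection. miR-1 is a microRNA best known from heart and skeletal muscle. The comparison asked which transcripts differ when this microRNA is supplied to a colorectal cancer line. The array measured messenger RNAs and did not measure mature miR-1, so the uptake of the precursor was not checked here. Each group had 1 array. Of the spots for human transcripts, 66.1% were well above background on the control array and 65.9% on the miR-1 array, and 0 spots were saturated on either. The 75th percentile of the processed signal was 559 on the control array and 550 on the miR-1 array. Over 26040 probes well above background on both arrays, the signals correlated at r = 0.994, a correlation across probes, which are not independent replicates. The spot SD of the log2 change had a median of 0.08, with 0.15 among the dimmest probes and 0.06 among the brightest. Among 17356 pairs of repeated spots on the same array, 0 differed by 2-fold or more. Spots flagged as outlying on either array, or not well above background on both, had been left out before pairing. The spot SDs rest on the same selected spots. The 0 is therefore no error rate for probes spotted once.

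After miR-1 precursor, more genes matched to the reference were at least 2-fold lower than 2-fold higher, a split that turned round with scaling on spike-in transcripts. The 7177 probes above background on both arrays that matched no reference gene leaned the other way, with 72 at least 2-fold higher and 49 lower. Of 12697 genes well above background on both arrays, 110 were at least 2-fold lower and 58 at least 2-fold higher, so that 65.5% of those past 2-fold were lower. At 1.5-fold the counts were 530 lower and 331 higher. Among the 6348 brighter of these genes, 23 were at least 2-fold lower and 8 at least 2-fold higher. Of the 110 lowered genes 39 had several measured probes, and in 34 of these all probes changed in the same direction, against 14 of 21 for raised genes. The normexp background correction, which compresses dim signals, left 39 lower and 19 higher, of which 37 and 18 were among the genes counted above. Scaling on 7 external spike-in transcripts raised every gene by 0.18 on the log2 scale and gave 61 lower and 109 higher (35.9% lower). All changes below are relative to the 75th percentile of each array.

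Among well-expressed genes the most lowered were LASP1, TAGLN2 and SERP1. LASP1, an actin-binding LIM protein, was 3.72-fold lower (log2 change -1.90), with a processed signal of 3742 on the control array and 990 on the miR-1 array (probe at chromosome 17, 34330990 to 34331049, hg17). SERP1, a protein of the endoplasmic reticulum membrane, was 3.67-fold lower, and its probes gave log2 changes from -2.19 to -1.88. TAGLN2, transgelin 2, was 3.32-fold lower (chromosome 1, 156701245 to 156701304, hg17). The spot SD at these signals was 0.07. The other genes among the 12 most lowered were dim on both arrays, and in each the control signal lay between 41.9 and 151. Among them, GAS7 was 12.9-fold lower, NR5A2 5.67-fold, FOXJ1 5.29-fold, GSG1 5.00-fold, PRR15L 4.77-fold, VILL 4.62-fold, LHFPL6 3.91-fold and MEGF11 3.25-fold. Each of these rested on 1 probe, at a spot SD of 0.15. Further lowered genes among the brighter ones were MTX1 (2.97-fold), SLC44A1 (2.65-fold, with probes from -1.41 to -0.25), the tetraspanin TSPAN4 (2.64-fold, probes from -1.40 to -1.35), S100A2 (2.59-fold), NELFCD (2.52-fold) and NETO2 (2.35-fold). The embryonic globin transcript HBE1 was 2.44-fold lower, with probes from -1.29 to -1.27.

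Under this scaling, raised genes matched to the reference were fewer than lowered ones and, like these, for the most part dim. PRRC2C was 2.89-fold higher, with probes from 0.93 to 1.53, and NEAT1, a long noncoding RNA of nuclear paraspeckles, was 2.54-fold higher, with probes from 1.35 to 1.56. LRP6, a Wnt co-receptor, was 5.67-fold higher on 1 probe, at signals of 84.6 and 472. CD86 was 2.95-fold higher and SCML1 2.87-fold, the latter with probes from 1.52 to 1.62. The remaining members of the 12 most raised were CHRNB3 (7.13-fold), DMBX1 (3.65-fold), RAB4B (3.39-fold, probes from 0.26 to 1.76), RNF112 (3.21-fold), FTMT (2.86-fold), CALHM6 (2.77-fold) and LHFPL5 (2.74-fold), all with a control signal between 9.54 and 74.5. Among brighter genes, SPOPL was 2.29-fold higher, DENND6A 2.28-fold, SNRPC, a protein of the U1 spliceosomal particle, 2.12-fold, the antiproliferative gene BTG3 2.11-fold and PMM2 2.07-fold. A further 250 genes were above background on the control array alone and 198 on the miR-1 array alone. Of these, FCN2 was at least 8.03-fold lower, CRYGB at least 7.29-fold, TRIM40 at least 6.97-fold and FILIP1 at least 6.24-fold. XAGE5 was at least 54.0-fold higher, GPR174 at least 34.4-fold, GYPE at least 32.7-fold and KLHL40 at least 26.8-fold, each on 1 probe. These bounds allow for the background but not for an error of a single probe on 1 array.

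**Figure D1:**
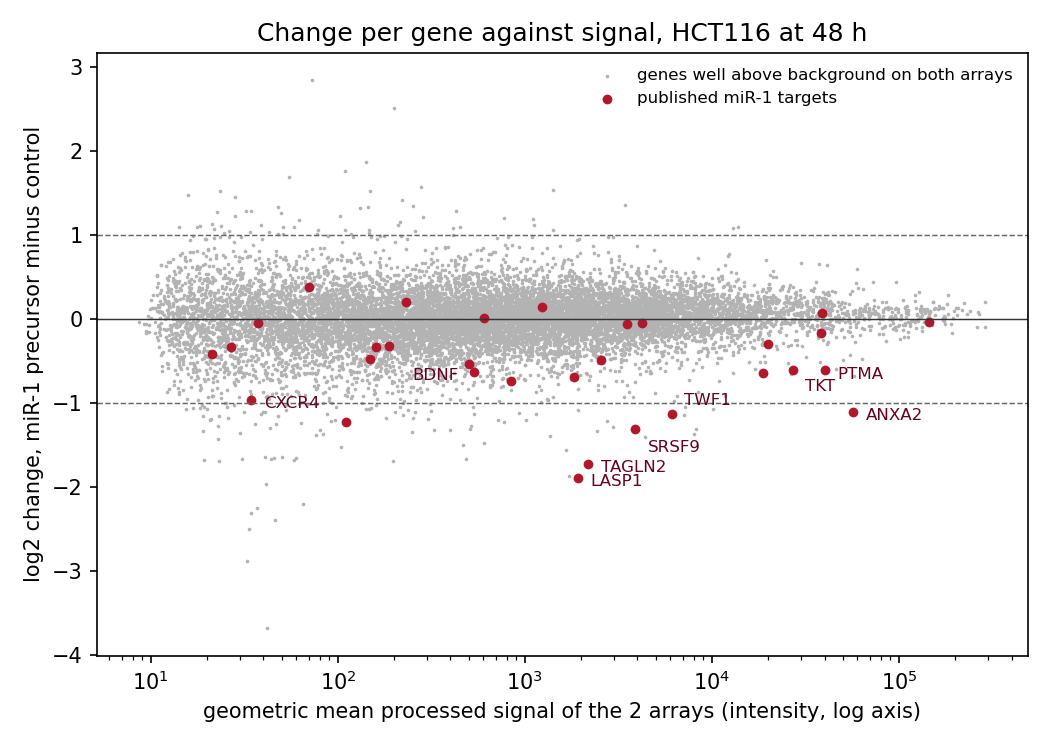
Each point is a gene well above background on both arrays, with the geometric mean of its processed signals (intensity, log axis) against its log2 change, miR-1 precursor minus control. Red points are published miR-1 targets, dashed lines mark 2-fold, and LASP1 at -1.90, TAGLN2 at -1.73 and ANXA2 at -1.11 lie below genes of similar signal.

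Transcripts previously described as miR-1 targets in various cell types were lower as a group. Of 33 measured members of this list, 28 were below 0, 14 were at least 1.5-fold lower, 7 of these at least 2-fold, and 0 were 1.5-fold higher. Their median log2 change was -0.48, below all 10000 matched random lists (percentile 0). Besides LASP1 and TAGLN2, the splicing factor SRSF9 was 2.49-fold lower, the actin-monomer binder TWF1 2.19-fold (probes from -1.13 to -0.96) and the calcium-dependent membrane-binding protein ANXA2 2.16-fold, at signals of 84091 and 38315 (chromosome 15, 58427038 to 58427097, hg17; 3 probes from -1.11 to -0.80). SLC8A1, above background on the control array alone, was at least 2.26-fold lower. CXCR4 was 1.95-fold lower, on 1 probe at dim signals of 48.6 and 24.5. The exportin XPO6 was 1.67-fold lower, CNN3 1.62-fold, PNP 1.56-fold, PTMA 1.53-fold and TKT 1.53-fold. The neurotrophin BDNF was 1.55-fold lower (chromosome 11, 27636476 to 27636535, hg17, with probes from -1.72 to -0.63). The receptor tyrosine kinase MET had a log2 change of -0.31, with 3 probes from -0.31 to -0.24. CCND1 (-0.06), HSPD1 (-0.04), HSPA4 (0.07), VEGFA (0.19) and MEF2A (0.37) were members without such a decrease. ANXA2 and BDNF may have been listed through work that rests on these arrays, which could not be checked here. For them the direction is not taken as independent evidence. Without them the median was -0.46, again at percentile 0.

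Genes of the actin cytoskeleton were lower relative to other genes, and a few strongly changed members led the list. Of 44 measured members 29 were below 0, 8 were at least 1.5-fold lower and 5 of these at least 2-fold, and 1 was 1.5-fold higher. Along with LASP1, TAGLN2 and TWF1, the actin-monomer binder TMSB4X was 2.34-fold lower, and the tropomyosin TPM3 2.49-fold by its brightest probe, which was also the most lowered of its probes. TPM3 had 8 probes from -1.31 to -0.45, and the files place its brightest probe on chromosome 2 (231262278 to 231262337, hg17) and the other probes on chromosome 1, so whether that probe measured TPM3 itself or a copy of it elsewhere is not known. WDR1 (-0.74, with probes from -0.81 to 0.35) and CORO1B (-0.61) were below 0 too, whereas TPM4 was at 0.73, ARPC4 at 0.56 and actin itself near 0 (ACTB -0.08, ACTG1 0.15). The list median was -0.15 (percentile 0), and 0.03 with spike-in scaling, under which the median of all genes was 0.19. Without the 4 members shared with the published targets it was -0.11 (percentile 0.04), and with the mean over each gene's probes it was -0.08.

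The pentose phosphate pathway, which supplies NADPH and ribose, had a lower median, and its lowered members included PGD and TKT, which are also on the target list. TKT, transketolase, had signals of 33682 and 21700, and PGD had a log2 change of -0.49. Of 7 measured members 5 were below 0 and 2 were at least 1.5-fold lower, with a median of -0.44 (percentile 0.03). This rested on the shared genes and on the choice of probe: without the 3 shared members the median was -0.04 (percentile 23.9), and with the mean over each gene's probes it was -0.14 (percentile 4.27). Glycolysis genes were close to 0, with 1 of 18 members at least 1.5-fold lower (PFKL, 1.66-fold) and a median of -0.06 (percentile 1.80), which was 0.12 with spike-in scaling. With no filter on dim probes the percentile was 2.54.

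Interferon-stimulated genes were lower after miR-1 precursor than after control precursor. Of 26 measured members 19 were below 0, 6 were at least 1.5-fold lower and 0 were 1.5-fold higher, and the median was -0.33 (percentile 0). The 10 brighter members had a median of -0.12 at percentile 5.86, inside the central range. MX1, an antiviral GTPase, was 2.69-fold lower, at signals of 38.0 and 13.9. IFITM1 was 1.68-fold lower, the oligoadenylate synthetase OAS3 1.63-fold with probes at -0.82 and -0.71, and the RNA sensor IFIH1 1.58-fold. ISG15 (0.18), ISG20 (0.40) and IRF7 (0.42) were not lower. Among NF-kappaB response genes, 0 of 11 were changed 1.5-fold and 8 were below 0, with a median of -0.21 (percentile 2.12). TNFAIP2 was at -0.49, CXCL1 at -0.48, BIRC3 at -0.53 and NFKBIA at 0.05. With no filter on dim probes the NF-kappaB median was -0.03 (percentile 11.5).

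Chaperones, unfolded protein response genes and cholesterol synthesis genes were higher, by small amounts in most members. Among heat shock proteins and chaperones, 20 of 24 were above 0, 2 were at least 1.5-fold higher and the median was 0.27 (percentile 100). The small heat shock protein HSPB1 was 1.58-fold higher, with 3 probes from 0.61 to 0.66, and HSP90AA1 had a log2 change of 0.59, with 4 probes from 0.37 to 0.81. HSPH1 was at 0.57, whereas HSPD1 (-0.04) and HSP90B1 (-0.19) were not higher. Of 18 genes of the ATF4 and unfolded protein response list 13 were above 0, with a median of 0.23 (percentile 99.95). DDIT3, a stress-induced transcription factor, was 2.52-fold higher, at signals of 160 and 397. DDIT4 was at 0.51, HSPA5, also on the chaperone list, at 0.38 and HERPUD1 at 0.36, while PSAT1 (-0.33) and PHGDH (-0.49), enzymes of serine synthesis, were below 0. Of 20 cholesterol synthesis and uptake genes 16 were above 0, with a median of 0.22 (percentile 99.95). The sterol carrier STARD4 was 1.98-fold higher and INSIG1 1.75-fold, SQLE was at 0.33, and 1 member of the list was at least 1.5-fold lower. Cytosolic ribosomal proteins had a median of 0.02 over 30 members (percentile 7.59), and of -0.02 (percentile 2.35) with quantile normalisation, with RPS2 at -0.10 and RPL13 at 0.13.

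**Figure D2:**
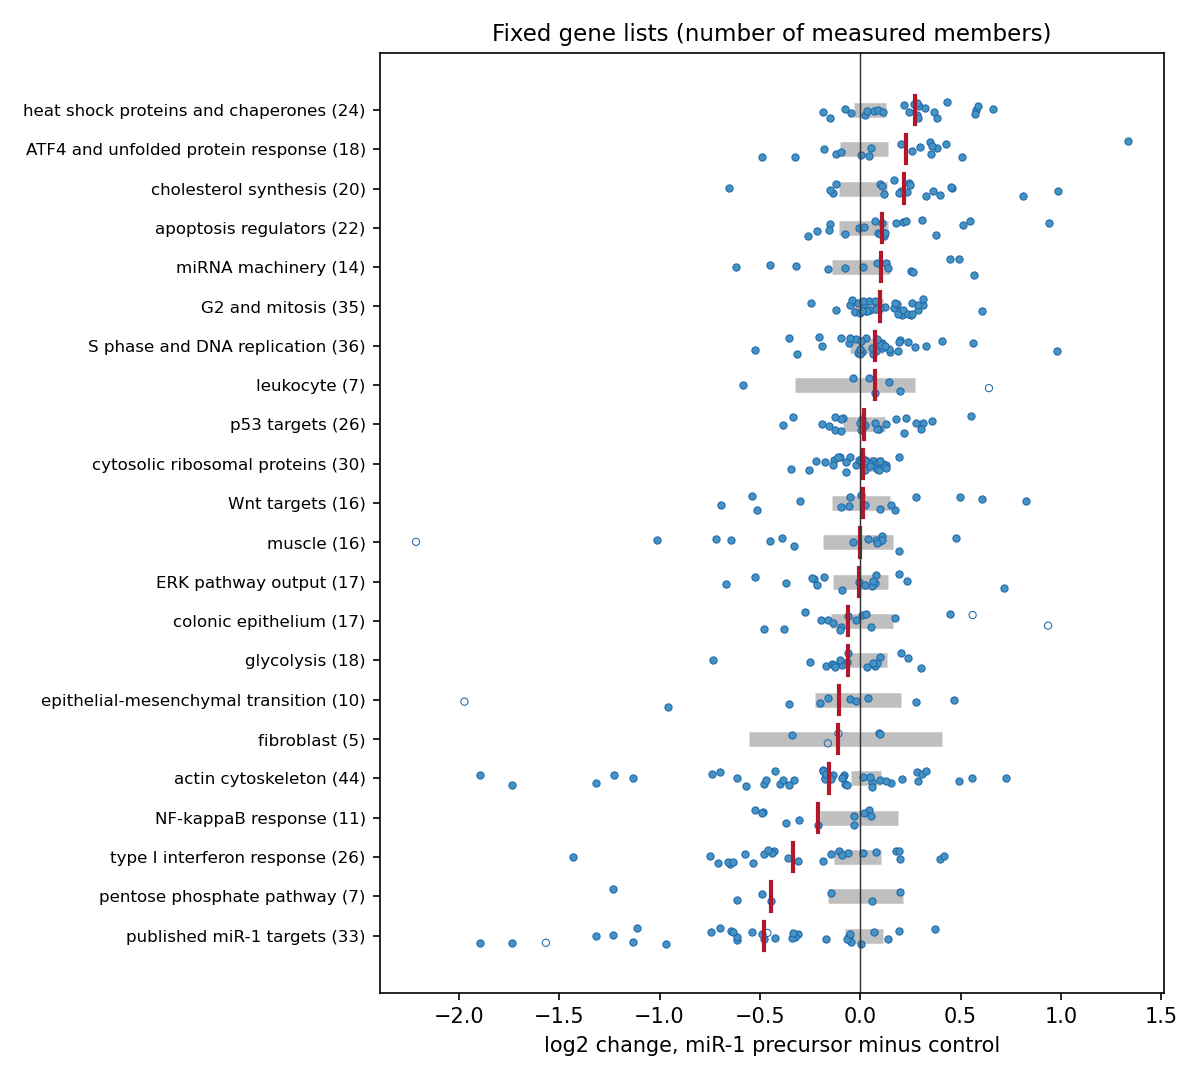
Log2 change, miR-1 precursor minus control, of each measured member (points) of the fixed lists, with the list median (red bar) and the central range of medians of matched random lists (grey band). Open points are genes above background on 1 array alone, at their measured values. The median is -0.48 for the published miR-1 targets, -0.15 for the actin cytoskeleton (0.03 with spike-in scaling) and 0.27 for chaperones.

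Proliferation and survival genes changed little. Of 36 S phase and DNA replication genes 1 was at least 1.5-fold higher, the replication factor GINS1 (1.97-fold), and the median was 0.07 (percentile 81.8). Of 35 G2 and mitosis genes 28 were above 0 and 1 was 1.5-fold higher, the kinesin KIF11 (1.52-fold, with a second probe at -0.07). Their median of 0.10 was at percentile 95.5, and at 98.3 with the normexp correction and 99.0 with the mean over each gene's probes. Among 26 p53 targets 0 were changed 1.5-fold and the median was 0.02 (percentile 51.9), with GDF15 at 0.22 and BBC3 at 0.13. The 22 apoptosis regulators had a median of 0.11 (percentile 92.7), and 1 was 1.5-fold higher, the BH3-only gene BMF (1.92-fold). BMF rested on 1 probe at signals of 11.9 and 22.4. The lowest signals well above background were 8.79 on the control array and 8.44 on the miR-1 array. ERK pathway output had a median of -0.00470 over 17 members (percentile 42.2; 0.18 with spike-in scaling and -0.11 with the mean over probes), with FOS 1.64-fold higher and SPRED1 1.59-fold lower. Wnt targets had a median of 0.01 over 16 members (percentile 51.1), with ASCL2 1.77-fold and RNF43 1.52-fold higher and EPHB2 1.62-fold lower. ASCL2 was dim, at signals of 15.3 and 26.6 on 1 probe. Among 14 genes of the microRNA machinery the RNA helicase MOV10 was 1.53-fold lower, the argonautes AGO2 (0.57), AGO4 (0.49) and AGO3 (0.45) were above 0, and the median was 0.10 (percentile 91.6), or 0.02 with the mean over each gene's probes.

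Markers of cell identity did not stand apart as groups. The colonic epithelium list had a median of -0.06 over 17 members (percentile 15.9, and 0.12 with spike-in scaling), and 0 members were changed 1.5-fold once bounds were used. CA1 was above background on the miR-1 array alone and at least 1.21-fold higher. Of 10 measured genes of epithelial-mesenchymal transition, 2 were at least 1.5-fold lower: the receptor tyrosine kinase AXL (1.94-fold) and SPARC (at least 2.17-fold, above background on the control array alone). Their median was -0.10 (percentile 16.2), but 0.08 with spike-in scaling and 0.00544 with no filter on dim probes. Muscle genes, 16 of which were measured, had a median of 0.000954 (percentile 53.1) and none was 1.5-fold higher. MB was at least 2.41-fold lower, TNNI1 2.02-fold, MYL2 1.65-fold and DES 1.56-fold, all at control signals between 20.6 and 51.7. The fibroblast list (5 measured, median -0.11, or 0.08 with spike-in scaling, percentile 33.5, THY1 at 0.10, COL6A3 at -0.34) and the leukocyte list (7 measured, median 0.07, percentile 71.3, ITGAM at least 1.56-fold higher) held few measured genes.

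Genes whose probe contained the miR-1 seed match were lower than genes without it. The word ACATTCC, complementary to positions 2 to 8 of miR-1, lay in the probes of 65 of 13153 genes. Their median log2 change was -0.14, against 0.01 for genes with no CATTCC, and 46 of them were below 0 (percentile 0). By the strongest class of site, the median was -0.14 for 15 genes with ACATTCCA (percentile 5.42), -0.15 for 50 with ACATTCC alone (percentile 0.01), -0.01 for 78 with CATTCCA (percentile 42.1) and 0.01 for 104 with CATTCC alone (percentile 44.6). Among the brighter genes, the median was -0.19 for 30 genes with ACATTCC, of which 76.7% were below 0, against 0.03 for 6450 genes with no CATTCC. One of these genes was the published target PNP. Among all hexamers, CATTCC ranked 465 of 4057 from the lowest mean difference, so the ranking over all genes did not single it out. By standardised difference it ranked 206. Among the 6576 brighter genes it ranked 46 of 3761 by mean difference (-0.09) and 2 by standardised difference, behind GTGCAG. Among the 6577 dimmer genes it ranked 1369 of 3773 by standardised difference. With no filter on dim probes the difference for ACATTCC was -0.06 and the standardised rank among the brighter genes 11.

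**Figure D3:**
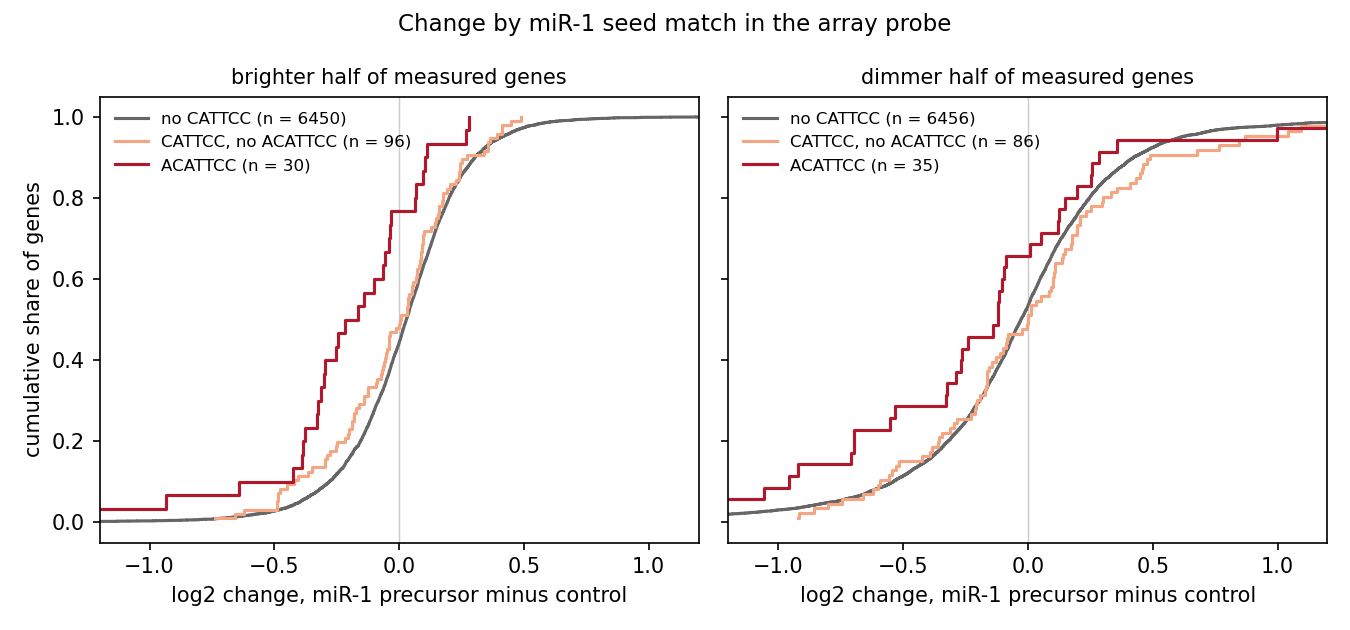
Cumulative share of genes against log2 change, miR-1 precursor minus control, for the brighter (left) and dimmer (right) measured genes, by the miR-1 seed match in the array probe. In the left panel the curve of 30 genes with ACATTCC lies to the left of the others, with a median of -0.19, while 96 genes with CATTCC but not ACATTCC have a median of 0.01.

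Seed matches of microRNAs common in epithelial cells, and of the passenger strand of miR-1, were searched in the same way, to ask whether targets of other microRNAs differed too. All classes but let-7, miR-19 and miR-21 had medians inside the central range of random lists. Relative to genes without the word, the median was 0.02 for the miR-17 family (percentile 73.2), -0.01 for the miR-200b family (43.4), -0.02 for miR-15/16 (20.6), -0.02 for miR-30 (26.7), -0.00343 for miR-29 (43.8), -0.0046 for the miR-103 family (46.3), 0.03 for miR-26 (80.0) and -0.01 for the passenger strand miR-1-5p (37.0). Genes with the let-7 match were higher by 0.09 (58 genes, percentile 99.0) and those with the miR-19 match by 0.08 (81 genes, percentile 99.3). Genes with the miR-21 match were lower by 0.16 (35 genes, percentile 0.59). With the normexp correction these differences were 0.05, 0.03 and -0.04.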

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

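Spike-in scaling, the nearest-spot correction, the lists without published targets and everything on words in probes were chosen after seeing the data. Spike-in scaling added 0.18 to every gene, which by construction put the actin median at 0.03 and the glycolysis median at 0.12 and left differences between lists as they were. In the other settings run no list median that stood apart changed sign, and no named gene changed at least 2-fold did so in any. The cause of each move was not tested unless stated. With the normexp correction, 19 genes were at least 2-fold higher and 39 lower, and medians were -0.32 for published targets, -0.26 for interferon genes and 0.16 for the unfolded protein response. CATTCC then ranked 69 by mean difference, and 1 among brighter genes by standardised difference, the measures used for these ranks throughout, and seed match differences were 0.0287 for miR-19, -0.0440 for miR-21, 0.0492 for let-7 and -0.0450 for the miR-103 family. Restricting to probes above background on both arrays gave ranks of 123 and 1. With no filter, 376 genes were higher and 452 lower, because dim probes entered the count, and values were -0.38 for published targets, -0.25 for interferon, -0.0315 for NF-kappaB, 0.00544 for epithelial-mesenchymal transition, -0.0612 for ACATTCC, -0.0187 for miR-21 and rank 11 among brighter genes. With the mean over a gene's probes, medians were -0.0754 for actin, -0.14 for the pentose phosphate pathway, -0.11 for ERK output, 0.23 for chaperones, 0.16 for the unfolded protein response, 0.019 for microRNA machinery and -0.0635 for miR-21. Spike-in scaling moved the median of all genes to 0.19, with 109 higher and 61 lower by construction. At 1.5-fold 331 were higher and 530 lower, and at 3-fold 5 and 22. The mean over members was -0.55 for published targets, -0.24 for actin, -0.29 for epithelial-mesenchymal transition and -0.29 for muscle. Without published targets the medians were -0.11 for actin and -0.0427 for the pentose phosphate pathway. Nearest-spot correction gave 0.21 for chaperones and -0.017 for ribosomal proteins, and quantile normalisation gave -0.017 for the latter. By standardised difference CATTCC ranked 206, and 159 with probe GC and mean signal in a linear model, which ranked it 1 among brighter genes. Of the values of named genes, 68 of 100 moved by more than the spot SD with the normexp correction and 22 of 100 with the mean over a gene's probes. The deposited value table and the subtraction of the spike-in shift could not move any value. The alternatives for the choice of 3′ untranslated region and its length were not run. No paired analysis was possible because each group had 1 array. Signal over background limited the dimmest genes, where the spot SD was 0.15.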

Other observations

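Beyond the published targets, several brighter genes with ACATTCC in their probe were lower, and they were picked out after their values were seen. RAB43, a small GTPase of the secretory pathway, had a log2 change of -1.21 (probes from -1.28 to 0.01), ARF3, another small GTPase, -0.93 (probes from -0.93 to -0.20), the actin regulator VASP -0.42 and ANXA1, a relative of ANXA2, -0.33. Among dimmer genes, the nucleoside transporter SLC29A3, with the longer word ACATTCCA, was at -0.92 (probes from -0.92 to -0.12). Array entries that matched no gene of the reference leaned the other way from named genes: of 7177 such probes above background on both arrays, 72 were at least 2-fold higher and 49 at least 2-fold lower.

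The patterns below were weighed with tests of array position, scaling, base composition and the composition of the word chosen after the results were seen, whereas the tests on brighter members and on the other probes of the same genes were set before their values were known.

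Interferon-stimulated genes were lower after miR-1 precursor. Error of single probes is argued against by the other probes of 8 members, whose median of -0.26 lay at percentile 0.90. A broad trend across the array is argued against by a median of -0.37 after subtracting the nearest spots. Defects covering fewer spots than the 200 used for each local median could not be removed by that step, so they stay open. Noise of dim probes stays open: the 10 brighter members had a median of -0.12 at percentile 5.86, inside the central range, although the whole list had been set against equally dim genes. Effects of the control precursor and of miR-1 both stay open and untested, since no array came from cells without precursor. With 1 array per group, a difference between the cultures unrelated to either precursor stays open too.

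Chaperone, unfolded protein response and cholesterol genes were higher. A single scaling factor for the whole array moves every gene alike, so it could not set these lists apart from genes of similar signal. The median of the ribosomal proteins was 0.015, but it has no bearing on where the 3 lists stand among matched random lists. Base composition of the probes is argued against by the lowest of the 3 percentiles among lists matched on expression and probe GC, 99.9. The other probes of 30 members had a median of 0.14 at percentile 98.5, carried mainly by 14 chaperones (percentile 98.6), while those of the unfolded protein response (9 genes, percentile 80.4) and cholesterol (8 genes, percentile 94.0) did not stand apart on their own. No biological explanation was tested, and with 1 array per group a difference between the cultures unrelated to miR-1 stays open.

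Genes with ACATTCC in the probe were lower. Base composition of the word is argued against, since among 205 words made of the same bases, it ranked 1, with a median of -0.14, though the next lowest word was also at -0.14. An effect on the single probe that holds the word stays open: the other probes of 30 of these genes had a median of -0.07, with 22 below 0, at percentile 6.68. Over the 29 genes where no other probe held CATTCC, the median was -0.09 at percentile 3.61, also inside the central range. A shift of this size was not particular to the miR-1 word in the main setting. Genes with the miR-21 match, of a microRNA that was not supplied, were lower by 0.16 (35 genes, percentile 0.59). That difference was smaller with the normexp correction. Lower levels of transcripts that pair with the miR-1 seed remain a hypothesis. Probe sequences alone, covering 60 bases of each transcript, leave it untested for most sites.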
